A study of Mus musculus with 6 samples.

How the data were processed

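The data are RNA sequencing libraries of 6 subcutaneous CT26 tumours, 3 from mice given the control peptide Scr-MAP and 3 from mice given the EMMPRIN peptide 161-MAP. Per the labels' protocols, total RNA with RNA integrity values from 6.5 to 10.0 was extracted on columns, and polyadenylated RNA was selected from 800 ng per tumour. Libraries were made with a kit taken from its catalogue number not to mark the strand, pooled at equal molarity and read as pairs of 75 bp. The integrity value of each tumour is not given in the sources used here. If the kit does not mark the strand, reads from exons that overlap exons of another gene on either strand cannot be told apart. Of the 99 named genes, 46 have a span, introns included, that overlaps another gene. Whether their exons overlap was not computed.

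Per the submitters' processing notes, the tools named were FastQC 0.11.2, cutadapt 1.8, TopHat2 2.0.13, HTSeq 0.6.1 and DESeq2 1.8.1, with the genome build GRCm38. The role and settings of each tool, the strand setting of the counting and the annotation are not given in the sources used here. The authors deposited a table of whole-number counts per gene, not normalised, and a table of FPKM per gene, both with 24421 rows and 1 column per tumour, and all columns were assigned to tumours by the number and group in their names. Of the rows, 7104 held 0 counts in all tumours. The FPKM values equal the deposited counts divided by a DESeq2 size factor and a length per gene, to a relative deviation of 1e-08 over 10602 genes with at least 20 counts in every library, so they carry no independent information. The length they imply has a median of 2921 bp over the tested genes and a Spearman rho of 0.773, across genes, with the exon length in the annotation. In the gene column, 27 symbols had been turned into dates by a spreadsheet, 2 of them in duplicate, and these were kept in the fits and never named.

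Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by its default filter by group with a smallest count of 10, which left 12244 genes, and libraries were scaled with TMM factors. The main test was the robust quasi-likelihood F test with the group as the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. CPM in the text are TMM-scaled, except sums over tissue lists, which are scaled by library size alone. Means are given with the SD over 3 tumours, and fold changes are 161-MAP over Scr-MAP. Total counts ran from 9141817 to 11232079 per tumour. The spread between tumours, with a common biological coefficient of variation of 0.370, limits the precision of abundant genes more than counting does, and intervals on counts cover counting error only. The label numbers of the 2 groups do not overlap, so no pairing was fitted. Group means of a single value were compared with an exact permutation test, two-sided, in which 3 against 3 cannot give a p below 0.1.

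Before the data were examined, 31 gene lists, the tests, the alternatives and the genes to be named were fixed. The lists cover EMMPRIN and its partners, immune cell types, macrophage states, antigen presentation, interferon-stimulated genes, chemokines, stroma, tumour cell programmes and tissues around a subcutaneous tumour. Lists with at least 5 measured members (26 of 31) were tested with camera of limma 3.58.1, with a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Named were Bsg, Vegfa, Mmp9 and Tgfb1, the 10 genes with the largest change in each direction past the test or, when none passed, the 5 with the smallest p in each direction, and the 3 measured members of each list with the smallest p. Unnamed gene models were skipped among the top genes. Of the genes picked in this way 2 are not reported here. The macrophage contrast is the mean log2(CPM + 1) of the M1-type list minus that of the M2-type list in a tumour. FPKM were tested with limma-trend on log2(FPKM + 1), for genes with an FPKM of at least 1 in 3 or more libraries.

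Alternatives fixed beforehand were other size factors (RLE, upper quartile, library size only, library sizes without the 20 most abundant genes), no filter or a CPM of at least 1 in 3 libraries, DESeq2 1.42.0, limma-voom, the test without robust estimation, a threshold of 0.1, a required log2 fold change above 1, a pseudocount of 0.1 and the removal of each tumour in turn. Added after the data were seen were edgeR's likelihood-ratio test, DESeq2 without each tumour, the removal of a trend on log2 gene length from each library through offsets (lowess span 0.3), and the macrophage contrast without 3 interferon-induced chemokines. Against TMM, scaling by library size alone shifted the median log2 fold change of all genes by 0.17, and the other scalings shifted it by less than 0.1. Genes were placed on GRCm38 with the GENCODE M21 annotation, in which 11786 of the tested genes (96.3%) had a single gene of their symbol.

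The tests were run on simulated counts with the means, library sizes and spread of these 6 tumours and 200 of 12244 genes changed. The quasi-likelihood test recovered 0% of genes changed 2-fold, 63.5% of those changed 4-fold and 85.5% of those changed 8-fold, with 8.63% false calls at 4-fold. DESeq2 recovered 13.5%, 83.5% and 92% of them, and 50%, 24.1% and 22.0% of its calls were false. Camera recovered all lists of 20 genes changed 2-fold and called 0.172% of unchanged lists, in data simulated without correlation between genes. The limma test used for FPKM, run on simulated values with 12095 genes, recovered 90% of genes raised 8-fold. These values were scaled by library size and not divided by gene length, so the share does not give the recovery on FPKM. Figures were drawn with matplotlib.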

Results

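Gene expression was measured by RNA sequencing in subcutaneous CT26 tumours of mice vaccinated with 161-MAP and of mice vaccinated with Scr-MAP. CT26 is a colon carcinoma cell line of BALB/c mice, the strain that carried the tumours. 161-MAP is a multiple antigenic peptide directed at EMMPRIN, a cell surface glycoprotein known to induce matrix metalloproteinases and VEGF, and Scr-MAP served as the control peptide. Peptide (50 µg, in Freund's adjuvant) was given on days 7, 14 and 21 after implantation, and tumours were taken on day 27. Each group had 3 tumours from 3 mice, named here by group and the number in the labels: Scr-MAP-2, Scr-MAP-5 and Scr-MAP-126, and 161-MAP-941, 161-MAP-943 and 161-MAP-945. Bulk tumour RNA holds transcripts of the cancer cells and of the host cells among them. The question was which transcripts, and markers of which cell types, differed after vaccination against EMMPRIN.

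Total counts were 10253396, 9141817 and 11018170 in Scr-MAP-2, Scr-MAP-5 and Scr-MAP-126, and 10139165, 11232079 and 10849262 in 161-MAP-941, 161-MAP-943 and 161-MAP-945. All 6 tumours were used as separate replicates, and no pair agreed within sampling noise (chi-square per degree of freedom of at least 25.0). 161-MAP-943 stood apart from the other tumours. Its mean Spearman correlation with them, across genes, was 0.881, against 0.920 to 0.948 for the others, and it held the far end of a first principal component with 46.0% of the variance. Ptprc, which encodes the leukocyte surface protein CD45, was at 364 CPM in 161-MAP-943 and at 52.7 to 94.6 CPM in the other 5 tumours. Scr-MAP-5 resembled 161-MAP-941 (rho 0.972 across genes) as closely as it resembled Scr-MAP-126 (rho 0.972).

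Bsg, the gene of EMMPRIN, was expressed in every tumour, at 643 ± 222 CPM (SD, n = 3) in Scr-MAP and 360 ± 84.9 CPM (SD, n = 3) in 161-MAP tumours. Its log2 fold change was −0.83 (SE 0.32), which did not pass edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment (adjusted p = 0.227, and 0.11 to 0.544 under the 20 alternatives), and the groups overlapped. Bsg lies on the plus strand of chromosome 10, from 79704491 to 79711969 (GRCm38), and is annotated as protein-coding. Mmp9, a gelatinase induced by EMMPRIN (chromosome 2, 164940780 to 164955850, plus strand), was at 41.6 ± 10.3 CPM in Scr-MAP and 16.9 ± 11.1 CPM in 161-MAP tumours (SD, n = 3). The 2 groups did not overlap for Mmp9, and its log2 fold change of −1.30 (SE 0.50) did not pass either (edgeR adjusted p = 0.231, and 0.103 to 0.544 under the alternatives). Vegfa (chromosome 17, 46016993 to 46032369, minus strand) was at 134 ± 15.6 CPM and 151 ± 95.2 CPM, and Tgfb1 (chromosome 7, 25687002 to 25705077, plus strand) at 110 ± 12.2 CPM and 118 ± 37.3 CPM (SD, n = 3). For both, the difference was smaller than the SD in 161-MAP tumours, and without 161-MAP-941 its sign turned, to log2 values of −0.49 for Vegfa and −0.10 for Tgfb1.

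The list of EMMPRIN and its partners had 21 measured members, of which 13 were higher and 8 lower in 161-MAP, and 0 passed the edgeR or the DESeq2 threshold. Flt1 and Kdr, which encode VEGF receptors, were at 19.8 ± 3.51 and 13.3 ± 3.42 CPM in Scr-MAP and at 32.6 ± 3.96 and 33.3 ± 18.1 CPM in 161-MAP tumours (SD, n = 3). Hif1a, the oxygen-regulated transcription factor, was at 141 ± 12.7 and 210 ± 48.7 CPM. The groups did not overlap for Flt1 and Hif1a, which were higher, nor for 4 members that were lower: Mmp9 and, named after their values were seen, Ppia, Ppib and Vegfb. Tested as a set with camera, the list did not differ from other genes (adjusted p = 0.702). Its median (0.18, and 0.03 to 0.49 without single tumours) and mean (0.24) log2 fold changes were above 0. The test, which compares the mean gene statistic of the list with that of all other genes, pointed down.

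**Figure D1:**
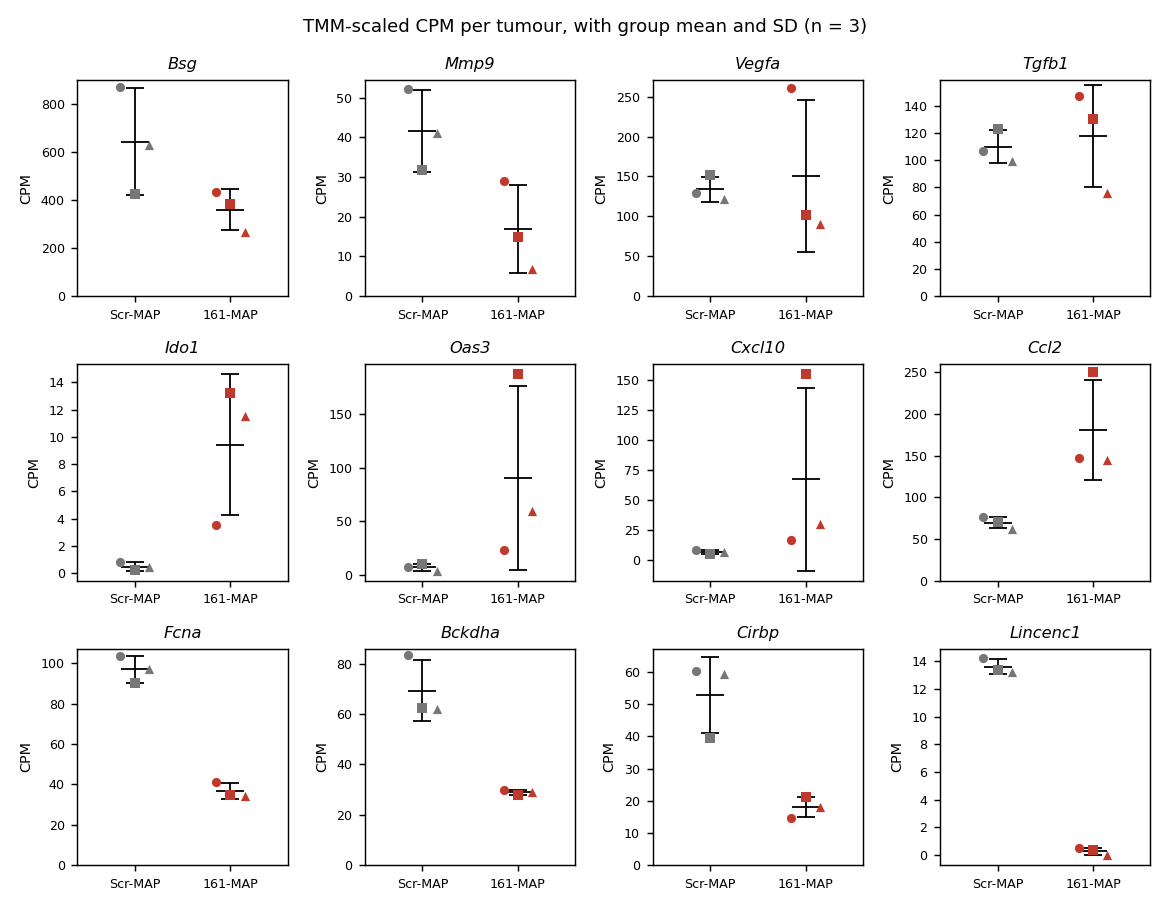
TMM-scaled CPM of 12 genes (y axes) in the 3 Scr-MAP tumours (grey) and the 3 161-MAP tumours (red), with the group mean and SD in black; circles, squares and triangles are Scr-MAP-2, Scr-MAP-5 and Scr-MAP-126 and 161-MAP-941, 161-MAP-943 and 161-MAP-945. Bsg overlaps between the groups, whereas Ido1, Oas3, Cxcl10 and Ccl2 are higher and Mmp9, Fcna, Bckdha, Cirbp and Lincenc1 lower in each 161-MAP tumour than in any Scr-MAP tumour.

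Across all genes, the tests differed in what they called. The planned edgeR quasi-likelihood test found 0 of 12244 genes at an adjusted p under 0.05 (lowest 0.216), with 2462 genes at an unadjusted p under 0.05, of which 1288 were higher and 1174 lower in 161-MAP and 612 were expected by chance. limma-voom also called 0 genes (2270 at an unadjusted p under 0.05). DESeq2 called 540 genes, 294 higher and 246 lower, of 11893 with an adjusted p, and edgeR's likelihood-ratio test called 204. In 507 of the 540 the groups did not overlap. Among all tested genes 3453 (28.2%) had groups that did not overlap, against 10% by chance. The 10% is a mean over splits of the tumours, and the share in each other split was not computed. The DESeq2 count moved with single tumours. It was 138 without Scr-MAP-2, 1019 without Scr-MAP-5, 56 without Scr-MAP-126, 1042 without 161-MAP-941, 429 without 161-MAP-943 and 209 without 161-MAP-945, and 239 of the 540 genes were also called without 161-MAP-943 and 128 without Scr-MAP-2.

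No gene having passed the planned test, the 5 genes with the smallest p in each direction are described as values. Higher in all 161-MAP tumours were Mcc (21.0 ± 2.61 against 52.6 ± 6.20 CPM), a regulator of Wnt signalling, Lyst (9.04 ± 2.04 against 24.9 ± 3.53 CPM), needed for lysosome traffic, and Stxbp5 (14.6 ± 1.30 against 31.0 ± 3.06 CPM), which encodes the syntaxin-binding protein tomosyn. Lrrtm2, an adhesion protein of synapses, was at 1.12 ± 0.49 and 12.4 ± 4.07 CPM, a log2 fold change of 3.47 (SE 0.51). Ido1, the interferon-induced enzyme that degrades tryptophan (chromosome 8, 24584136 to 24597009, minus strand), was at 0.499 ± 0.306 and 9.44 ± 5.18 CPM, a log2 fold change of 4.22 (SE 0.72). Lower in all 161-MAP tumours were Fcna, which encodes the macrophage lectin ficolin A (97.0 ± 6.76 against 36.6 ± 3.77 CPM), Bckdha, a subunit of the branched-chain keto acid dehydrogenase (69.4 ± 12.1 against 28.9 ± 0.947 CPM), Cirbp, the cold-inducible RNA-binding protein (53.0 ± 11.8 against 17.98 ± 3.17 CPM), and Faim2, an inhibitor of Fas-mediated apoptosis (6.31 ± 1.41 against 0.483 ± 0.287 CPM; SD, n = 3 throughout). Lincenc1, a long non-coding RNA known from embryonic stem cells, was at 13.6 ± 0.534 CPM in Scr-MAP and 0.277 ± 0.252 CPM in 161-MAP tumours (SD, n = 3), with 389 counts in all against 9. All 10 had an edgeR adjusted p of 0.216, stayed above 0.15 under the 17 alternatives other than DESeq2 and the likelihood-ratio test (0.152 to 0.522), and passed DESeq2 at 3.26e-14 to 0.00167. The spans of Fcna, Bckdha, Mcc, Lrrtm2 and Stxbp5, introns included, overlap those of Fcnaos, B3gnt8, A930012L18Rik, Ctnna1 and Gm25635. If the kit does not mark the strand, reads from any shared exon sequence cannot be told apart, and overlap of exons was not computed.

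Interferon-stimulated genes were higher in 161-MAP tumours than in Scr-MAP tumours. All 32 measured members of the list were higher, with a median log2 fold change of 2.24, and in 23 of the 32 the groups did not overlap. The mean of the list on the log2(CPM + 1) scale was 4.80, 4.10 and 4.28 in Scr-MAP-2, Scr-MAP-5 and Scr-MAP-126, and 5.09, 7.57 and 5.94 in 161-MAP-941, 161-MAP-943 and 161-MAP-945 (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 can give). Oas3, an antiviral sensor of double-stranded RNA, was at 7.24 ± 3.06 CPM in Scr-MAP and 90.2 ± 85.8 CPM in 161-MAP tumours, and Rsad2, which encodes the antiviral enzyme viperin, at 8.56 ± 3.16 and 41.3 ± 25.5 CPM (SD, n = 3). Of the 32 members, 0 passed edgeR's quasi-likelihood test over all genes, 28 passed when adjusted over the list alone, and 25 passed DESeq2. Camera gave the list an adjusted p of 1.77e-19 with its preset correlation, and adjusted p = 0.831 with an estimated correlation. Without 161-MAP-943, whose Ptprc level was the highest, the median was 1.20 and the preset adjusted p 1.22e-18, while 12 members passed DESeq2, as did 12 without Scr-MAP-2.

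Lymphocyte markers were higher mainly in 161-MAP-943. All 16 measured T cell markers, 12 of 13 cytotoxic lymphocyte genes and all 8 NK cell markers had positive log2 fold changes, with medians of 2.37, 1.71 and 2.16. Il2rb, a receptor chain for IL-2 and IL-15, was at 13.4 ± 4.46 CPM in Scr-MAP tumours (SD, n = 3) and at 15.9, 134 and 57.0 CPM in 161-MAP-941, 161-MAP-943 and 161-MAP-945. Klrk1, which encodes the activating receptor NKG2D, was at 4.23 ± 1.69 CPM in Scr-MAP tumours (SD, n = 3) and at 2.65, 71.2 and 14.6 CPM in the 161-MAP tumours. Ncr1, Klre1, Eomes, Nkg7 and Cd27 showed the same order, with 161-MAP-943 at 19.5, 8.53, 13.1, 67.8 and 10.1 CPM and Scr-MAP means of 1.98, 0.748, 1.67, 6.39 and 0.752 CPM. The 3 lists passed camera at adjusted p of 0.000217 (T cell), 0.00995 (cytotoxic) and 0.0169 (NK), each with adjusted p = 0.831 with an estimated correlation. By list means of the tumours, the exact permutation p was 0.3 for each of the 3 lists. Without 161-MAP-943 the calls ended, with medians of 0.48, 0.66 and 0.97 and adjusted p of 0.0743, 0.357 and 0.333, and without Scr-MAP-5 the cytotoxic and NK calls ended at adjusted p of 0.156 with medians of 1.64 and 1.78. The genes that DESeq2 called included Cd28 among the T cell markers, Klrk1 among the cytotoxic genes and Il2rb among the NK markers, and it called 0 members of these lists without 161-MAP-943 or without Scr-MAP-2. Without Scr-MAP-2 the list medians were larger, at 2.65, 2.31 and 2.51, and camera's preset adjusted p smaller (1.12e-05, 4.07e-05 and 0.000226).

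The regulatory T cell and checkpoint list followed the lymphocyte lists. Of its 13 measured members 12 were higher (median 1.34), and Il2ra, Havcr2 and Cd274, which encode CD25, TIM-3 and PD-L1, were at 0.501 ± 0.179, 6.66 ± 3.35 and 19.5 ± 6.66 CPM in Scr-MAP and 3.82 ± 4.45, 21.2 ± 15.3 and 68.9 ± 66.0 CPM in 161-MAP tumours (SD, n = 3). The groups did not overlap for Il2ra and Havcr2, and 0 members passed edgeR or DESeq2. The list passed camera at an adjusted p of 0.0421, with adjusted p = 0.831 with an estimated correlation, and its tumour means gave an exact permutation p of 0.4. The camera call ended without 161-MAP-943 (median 0.06, adjusted p = 0.675). It also ended without Scr-MAP-5 (median 1.05, adjusted p = 0.362) and with scaling by library size alone (median 1.58, adjusted p = 0.0626). B and plasma cell markers had 3 measured members: Cd79a at 5.70 ± 4.84 and 1.20 ± 1.33 CPM, Tnfrsf17 at 1.47 ± 0.18 and 0.721 ± 0.221 CPM and Cd79b at 0.985 ± 0.448 and 3.33 ± 4.66 CPM in Scr-MAP and 161-MAP (SD, n = 3). Without 161-MAP-943 DESeq2 called Cd79a lower in 161-MAP (adjusted p = 0.00329). Immunoglobulin and T cell receptor constant genes were not analysed here.

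Monocyte and macrophage markers were split in direction. Of 18 monocyte and macrophage markers, 8 were higher and 10 lower, and camera gave an adjusted p of 0.401, with a median of −0.10 (0.06 with scaling by library size alone, 0.13 without 161-MAP-941 and 0.15 without 161-MAP-945) and a mean of 0.16 of opposite sign. Ly6c2 and Ccr2, markers of inflammatory monocytes, were higher in each 161-MAP tumour and passed DESeq2. Without 161-MAP-943 only Ly6c2 kept its call (adjusted p = 0.00013), while Ccr2 had a log2 fold change of 0.67 against 1.75 with all tumours (DESeq2 adjusted p = 0.126). Ly6c2 was at 3.03 ± 0.952 CPM in Scr-MAP (SD, n = 3) and 10.7, 148 and 25.6 CPM in 161-MAP-941, 161-MAP-943 and 161-MAP-945. Ccr2, the receptor of Ccl2, was at 34.7 ± 4.52 CPM (SD, n = 3) and 47.1, 241 and 62.7 CPM. Ly6c2 has a near-identical neighbour, Ly6c1, with which it can share reads. Cx3cr1, the fractalkine receptor, was at 36.7 ± 31.7 and 10.4 ± 3.00 CPM (SD, n = 3). Without 161-MAP-943, which carried the highest Ptprc, the list was lower in 161-MAP (median −0.67, camera adjusted p = 0.000234, and 0.000234 to 0.886 over the 13 alternatives), and DESeq2 then called 6 members lower and 1 higher. With all tumours an estimated correlation gave a camera adjusted p of 0.882.

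Genes of macrophage states were compared as the mean log2(CPM + 1) of the inflammatory (M1-type) list minus that of the alternative (M2-type) list in each tumour. Bulk tumour RNA does not show which cells held these transcripts, so the contrast is not a measure of macrophages alone. The difference was −1.26 ± 0.21 in Scr-MAP and −0.57 ± 0.02 in 161-MAP tumours (SD, n = 3), so M1-type genes stood 0.69 log2 units higher relative to M2-type genes in 161-MAP. The 3 161-MAP tumours lay between −0.59 and −0.55 and the Scr-MAP tumours between −1.44 and −1.02 (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 can give). Part of it came from Cxcl9, Cxcl10 and Cxcl11, chemokines induced by interferon, without which the difference was 0.27 (exact permutation p = 0.2).

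Of the 13 measured M1-type genes 12 were higher (median log2 fold change 0.93, and 0.45 without 161-MAP-943). The list passed camera at an adjusted p of 0.0436, with adjusted p = 0.831 with an estimated correlation, and its tumour means gave an exact permutation p of 0.2. Cxcl10 was at 6.49 ± 1.69 and 67.0 ± 76.2 CPM, Cxcl11 at 1.68 ± 0.799 and 20.4 ± 25.3 CPM and Tnf at 0.763 ± 0.189 and 2.97 ± 3.19 CPM in Scr-MAP and 161-MAP (SD, n = 3), and the groups did not overlap for Cxcl10 and Cxcl11, which both passed DESeq2, Cxcl10 also without 161-MAP-943. The camera call ended without Scr-MAP-5, Scr-MAP-126 or 161-MAP-943 (adjusted p of 0.169, 0.102 and 0.357, medians of 1.09, 0.92 and 0.45), with scaling by library size alone (0.0626, median 1.03) and when genes held by more than 1 list were left out (0.309, median 0.80). Of the 15 measured M2-type genes 9 were higher and 6 lower (median 0.25, and −0.04 without 161-MAP-941), and the list did not differ from other genes (camera adjusted p = 0.919). Within it Mrc1, the mannose receptor, was at 456 ± 69.7 and 328 ± 32.8 CPM without overlap, whereas Chil3 and Pdcd1lg2 (PD-L2) were at 0.29 ± 0.309 and 0.558 ± 0.43 CPM in Scr-MAP and at 3.25 ± 3.31 and 4.38 ± 4.29 CPM in 161-MAP tumours (SD, n = 3). Chil3 passed DESeq2.

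Neutrophil, dendritic cell and mast cell lists did not pass camera (adjusted p = 0.223, 0.0749 and 0.283). Of 13 neutrophil markers 11 were higher (median 1.23, and 0.57 without 161-MAP-943 and 0.76 without Scr-MAP-5), and Lcn2 was at 46.9 ± 48.2 and 10.95 ± 6.67 CPM, Csf3r at 10.8 ± 2.91 and 28.2 ± 22.8 CPM and Mmp8 at 1.45 ± 1.06 and 6.48 ± 5.19 CPM (SD, n = 3). Of 11 dendritic cell markers 10 were higher (median 1.34, and −0.08 without 161-MAP-943). Ly75, the endocytic receptor DEC-205, was at 16.8 ± 9.09 and 51.4 ± 19.9 CPM and Flt3 at 0.304 ± 0.138 and 3.50 ± 3.91 CPM (SD, n = 3), with no overlap of the groups, and both passed DESeq2 and edgeR's test adjusted over the list alone, but not over all genes. Without 161-MAP-943 DESeq2 called Ly75 and not Flt3, and 1 member lower, and without Scr-MAP-2 it called 0. Clec9a, a marker of cross-presenting dendritic cells, was at 0.921 ± 0.255 and 4.16 ± 3.54 CPM. The mast cell proteases Cpa3, Cma1 and Tpsab1 were at 2.01 ± 1.18, 2.24 ± 1.12 and 4.91 ± 1.48 CPM in Scr-MAP tumours (SD, n = 3) and at 67.4, 60.2 and 94.7 CPM in 161-MAP-943 alone, and the median of that list was 2.71 with all tumours and −0.14 without 161-MAP-943. With an estimated correlation and all tumours each of the 3 lists had adjusted p = 0.831. Some alternatives made them pass camera with its preset correlation, and an estimated one was not run for these alternatives. The neutrophil list passed without Scr-MAP-2 or 161-MAP-945 (adjusted p of 0.0436 and 0.000536), the dendritic cell list without Scr-MAP-126, 161-MAP-941 or 161-MAP-945 (0.0476, 0.000471 and 0.0134) and the mast cell list without 161-MAP-941 (0.0014). With a trend on gene length removed the neutrophil and dendritic cell lists passed as well (0.0394 and 0.041).

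Genes of antigen presentation were highest in 161-MAP-943, with list means of 8.17 (class I) and 7.97 (class II) on the log2(CPM + 1) scale, against 6.40 to 7.27 and 3.996 to 6.56 in the other tumours. Of 17 MHC class I presentation genes 14 were higher (median 0.67, and 0.03 without 161-MAP-943, where the adjusted p was 0.928). Camera gave an adjusted p of 0.0556, with 0.000226 to 0.928 over the alternatives and 0.831 with an estimated correlation and all tumours. With its preset correlation the list passed without Scr-MAP-2, 161-MAP-941 or 161-MAP-945 (0.000421, 0.000471 and 0.0105). It also passed with a trend on gene length removed (median 0.83, 0.000226). Nlrc5, the transactivator of class I genes, was at 21.6 ± 4.90 and 69.0 ± 47.7 CPM without overlap and passed DESeq2, though not without 161-MAP-943, and Tapbpl and Erap1 were at 22.3 ± 3.55 and 73.3 ± 6.39 CPM in Scr-MAP and 49.3 ± 22.6 and 115 ± 47.2 CPM in 161-MAP (SD, n = 3). Of 10 MHC class II presentation genes 9 were higher (median 0.88, camera adjusted p = 0.696). Without 161-MAP-943 the class II list was lower in 161-MAP, with a median of −0.98 and an adjusted p of 0.0279 (0.0279 to 0.982 over the alternatives). Without 161-MAP-941 it was higher at 0.0328, and with all tumours an estimated correlation gave 0.948. Ciita, the class II transactivator, was at 3.47 ± 1.39 CPM in Scr-MAP tumours (SD, n = 3) and at 1.18, 48.9 and 9.19 CPM in 161-MAP-941, 161-MAP-943 and 161-MAP-945. H2-DMb1 and H2-DMb2, close paralogs that can share reads, were at 14.8 ± 10.9 and 7.65 ± 3.94 CPM in Scr-MAP and 29.4 ± 39.2 and 17.0 ± 21.9 CPM in 161-MAP (SD, n = 3).

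Among 24 measured chemokines 16 were higher and 8 lower (median 1.16, camera adjusted p = 0.318). The median was −0.24 without 161-MAP-943, and the list passed without 161-MAP-945 (adjusted p = 0.00685) and with a trend on gene length removed (median 1.81, adjusted p = 0.00648). With all tumours an estimated correlation gave a camera adjusted p of 0.882. Ccl2, which recruits monocytes, was at 69.5 ± 6.92 CPM in Scr-MAP and 181 ± 60.2 CPM in 161-MAP tumours (SD, n = 3), a log2 fold change of 1.38 (SE 0.26) that passed edgeR's test adjusted over the list alone, though not over all genes (adjusted p = 0.216). Ccl12, another ligand of Ccr2, went the other way, at 68.9 ± 9.54 and 38.8 ± 10.4 CPM, also without overlap. Its log2 fold change was −0.83, and ran from −1.06 to −0.15 over the alternatives. DESeq2 called Ccl2, Cxcl10 and Cxcl11, all higher, and without 161-MAP-943 it called 2 members higher and 3 lower.

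Markers of vessels and matrix were high in 161-MAP-943. Of 22 endothelial and angiogenesis genes 17 were higher (median 0.71, camera adjusted p = 0.0502, median 0.02 without 161-MAP-943). The list passed without Scr-MAP-2, Scr-MAP-126, 161-MAP-941 or 161-MAP-945 (adjusted p of 0.00322, 0.0214, 0.000497 and 0.00685). It also passed with a trend on gene length removed (0.0459) and with a CPM of at least 1 in 3 libraries (0.04997). With all tumours an estimated correlation gave 0.831. Mmrn2, a matrix protein of endothelium, was at 9.83 ± 0.891 CPM in Scr-MAP (SD, n = 3) and at 9.72, 56.5 and 17.98 CPM in 161-MAP-941, 161-MAP-943 and 161-MAP-945. Of 22 fibroblast and matrix genes 21 were higher (median 1.36, camera adjusted p = 0.323, passing without 161-MAP-941 or 161-MAP-945 at 0.0127 and 0.00457). Col1a1 and Col3a1, the main fibrillar collagens, were at 175 ± 68.5 and 254 ± 139 CPM in Scr-MAP tumours (SD, n = 3), and at 3125 and 6113 CPM in 161-MAP-943 against 74.0 and 63.9 CPM in 161-MAP-941 and 206 and 101 CPM in 161-MAP-945. Col5a1 was at 88.3 ± 14.3 CPM in Scr-MAP (SD, n = 3) and at 83.9, 466 and 99.1 CPM in 161-MAP-941, 161-MAP-943 and 161-MAP-945. Without 161-MAP-943 the fibroblast list was lower in 161-MAP (median −0.80, camera adjusted p = 1.42e-06, and 1.42e-06 to 0.882 over the alternatives, the latter with an estimated correlation), and DESeq2 then called 6 of its members lower and 0 higher.

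**Figure D2:**
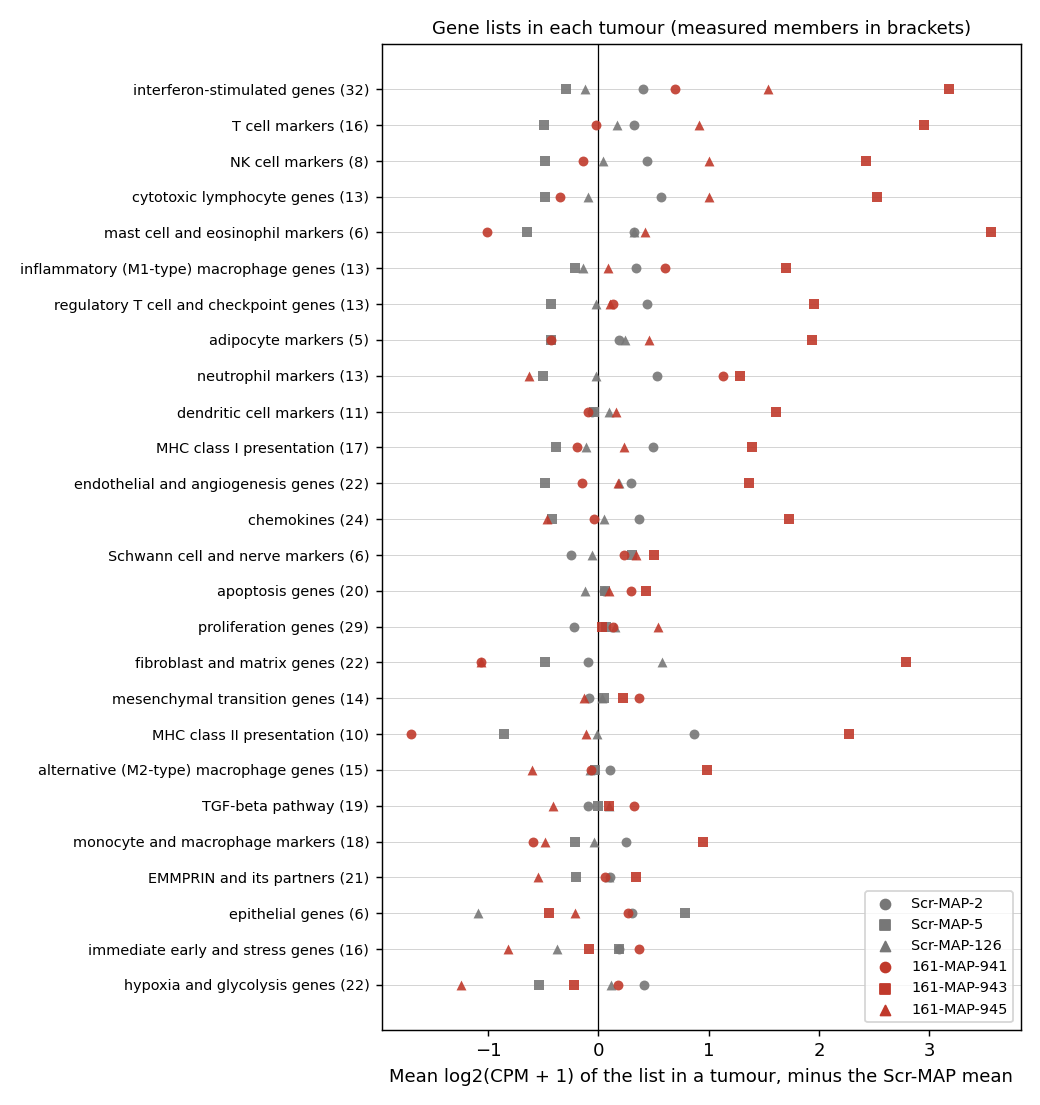
Mean log2(CPM + 1) of the measured members of each of 26 gene lists (y axis, number of members in brackets) in each tumour, minus the mean of the 3 Scr-MAP tumours (x axis, log2 units); Scr-MAP tumours are grey and 161-MAP tumours red. For interferon-stimulated genes every 161-MAP tumour lies to the right of every Scr-MAP tumour, whereas for T cell, MHC class II and fibroblast lists 161-MAP-943 (red square) lies far from the other 2 161-MAP tumours.

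Snai2, Prrx1 and Zeb2, transcription factors of mesenchymal transition, were higher in each 161-MAP tumour than in any Scr-MAP tumour. Snai2 was at 9.12 ± 1.32 and 23.2 ± 7.72 CPM, Prrx1 at 180 ± 66.5 and 360 ± 65.6 CPM and Zeb2 at 105 ± 19.4 and 173 ± 27.9 CPM in Scr-MAP and 161-MAP (SD, n = 3). Snai2 and Prrx1 passed DESeq2, Prrx1 also without 161-MAP-943 and neither without Scr-MAP-2, and Snai2 passed edgeR's test adjusted over the list alone. S100a4, named for its DESeq2 call after its values were seen, was called lower. The whole list of 14 genes, 9 higher and 5 lower, did not differ from other genes (median 0.16, and −0.01 without 161-MAP-941 and 0.37 without 161-MAP-945, camera adjusted p = 0.318). The TGF-beta pathway list of 19 genes was split into 10 higher and 9 lower (median 0.07, and −0.26 with a trend on gene length removed, camera adjusted p = 0.919). Tgfb3 was at 27.3 ± 1.43 and 39.6 ± 7.99 CPM without overlap, Ctgf at 46.8 ± 35.6 and 13.9 ± 7.27 CPM and Inhba at 6.50 ± 2.54 and 15.2 ± 11.1 CPM (SD, n = 3).

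Of 22 hypoxia and glycolysis genes 17 were lower in 161-MAP, with a median log2 fold change of −0.36 (camera adjusted p = 0.0328). List means on the log2(CPM + 1) scale overlapped between the groups (exact permutation p = 0.6). They were 7.60, 6.65 and 7.30 in Scr-MAP-2, Scr-MAP-5 and Scr-MAP-126, and 7.36, 6.96 and 5.94 in 161-MAP-941, 161-MAP-943 and 161-MAP-945. With an estimated correlation the adjusted p = 0.831, and the call also ended without Scr-MAP-2, Scr-MAP-126, 161-MAP-943 or 161-MAP-945 (adjusted p of 0.192, 0.0586, 0.0571 and 0.572, medians of −0.12, −0.31, −0.30 and −0.11). The median was −0.18 with scaling by library size alone and −0.21 with a trend on gene length removed, and the list passed under both (adjusted p of 0.0148 and 0.019). Ankrd37, a target of HIF-1, was at 11.99 ± 5.71 and 4.54 ± 2.62 CPM, Pfkl, a phosphofructokinase, at 202 ± 44.1 and 132 ± 49.2 CPM and Pdk1, which restrains pyruvate entry into mitochondria, at 50.6 ± 19.6 and 30.7 ± 12.1 CPM (SD, n = 3). None of the 3 passed edgeR or DESeq2.

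Of 29 proliferation genes 22 were higher (median 0.24), and camera gave an adjusted p of 0.0761. The list passed without 161-MAP-943 (adjusted p = 0.00374) and without Scr-MAP-126 (adjusted p = 0.0214) and with a trend on gene length removed (adjusted p = 0.0293), with a range of 0.00374 to 0.903 over the alternatives (0.831 with an estimated correlation), and the median was 0.09 without 161-MAP-945. Mki67 and Foxm1, which mark and drive cell division, were at 124 ± 32.5 and 106 ± 31.1 CPM in Scr-MAP and at 211 ± 33.0 and 188 ± 49.1 CPM in 161-MAP tumours (SD, n = 3), without overlap. The replication licensing gene Mcm7 was at 270 ± 24.7 and 190 ± 31.8 CPM, also without overlap and in the other direction. Of 20 apoptosis genes 12 were higher (median 0.32, and 0.18 with a trend on gene length removed, camera adjusted p = 0.166), with list means of 5.27 to 5.44 in Scr-MAP and 5.48 to 5.82 in 161-MAP tumours on the log2(CPM + 1) scale (exact permutation p = 0.1). Xiap, an inhibitor of apoptosis, was at 66.0 ± 23.9 and 130 ± 16.6 CPM and Birc3, another, at 12.5 ± 2.18 and 33.7 ± 25.7 CPM (SD, n = 3). None of these 5 genes passed edgeR or DESeq2.

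Of 6 measured epithelial genes 3 were higher and 3 lower (camera adjusted p = 0.318, pointing down, with a mean of −0.95 and a median of 0.03 that was −0.93 without 161-MAP-941). Cdx2, the intestinal homeobox factor, was at 1.78 ± 0.726 CPM in Scr-MAP tumours (SD, n = 3), with 50 counts in all, and had 1 count in all in 161-MAP tumours. It passed edgeR's test adjusted over the list alone, not over all genes, and has no DESeq2 adjusted p. Krt8 was at 22.8 ± 30.2 and 4.19 ± 3.49 CPM and Cdh1 at 0.873 ± 0.486 and 1.83 ± 1.65 CPM (SD, n = 3). Of 16 immediate early and stress genes, which respond to tissue handling, 7 were higher and 9 lower (median −0.05, and 0.13 with scaling by library size alone, camera adjusted p = 0.363). Without 161-MAP-941 this list was lower, with a median of −0.52 and an adjusted p of 0.0127 (0.0127 to 0.882 over the alternatives, the latter with an estimated correlation). Fosb was at 23.7 ± 13.8 and 11.3 ± 2.16 CPM, Egr3 at 7.10 ± 5.75 and 17.3 ± 8.86 CPM and Dusp1 at 54.9 ± 31.4 and 29.3 ± 17.9 CPM (SD, n = 3).

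Lists for tissue around the tumours had few measured members. Skeletal muscle had 3, of which Tnni2, a fast muscle troponin, was at 11.7 ± 4.45 and 1.21 ± 0.799 CPM (SD, n = 3), without overlap. Tnni2 passed DESeq2, also without 161-MAP-943 and without Scr-MAP-2, and passed edgeR's test adjusted over the list alone. The other muscle genes summed to 2.81 to 8.09 CPM in Scr-MAP and 4.93 to 8.46 CPM in 161-MAP tumours, scaled by library size alone. Ryr1 was at 1.248 ± 0.768 and 2.26 ± 0.854 CPM and Ttn at 1.599 ± 2.04 and 1.02 ± 0.665 CPM (SD, n = 3). Keratinocyte and skin markers had 3, Krt10 at 3.73 ± 1.28 and 4.85 ± 0.262 CPM, Lgals7 at 288 ± 132 and 207 ± 102 CPM and Sfn at 0.778 ± 0.392 and 0.949 ± 0.689 CPM (SD, n = 3). All 5 measured adipocyte markers were higher (median 0.81, and 0.33 without 161-MAP-943, camera adjusted p = 0.318), with Lpl at 5.50 ± 4.64 CPM in Scr-MAP (SD, n = 3) and 0.982, 236 and 5.12 CPM in 161-MAP-941, 161-MAP-943 and 161-MAP-945. Plin4 was at 2.53 ± 0.272 and 4.44 ± 1.55 CPM and Pparg at 1.77 ± 0.97 and 6.74 ± 7.98 CPM (SD, n = 3). The erythroid list had 2, Alas2 at 9.91 ± 1.79 and 3.62 ± 2.56 CPM, without overlap, and Bpgm at 11.9 ± 0.249 and 10.7 ± 1.81 CPM. Of 6 Schwann cell and nerve markers 4 were higher (median 0.56, and 0.09 without 161-MAP-941 and 0.34 without 161-MAP-943, camera adjusted p = 0.401), with Mbp at 2.43 ± 0.347 and 8.58 ± 9.41 CPM, Cnp at 17.6 ± 1.33 and 33.7 ± 25.3 CPM and Egr2 at 8.96 ± 2.76 and 13.1 ± 8.66 CPM (SD, n = 3). Mitochondrially encoded genes were not analysed here.

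Over the 26 lists with at least 5 measured members, camera with its preset correlation called 7, of which 6 were higher and 1 lower in 161-MAP, and called 0 with an estimated correlation and 13 with a trend on gene length removed. The rotation test fry, which asks whether the genes of a list move 1 way on balance, called 0 (lowest adjusted p = 0.671). The tumour means of 4 of the 30 lists with measured members did not overlap between the groups (interferon-stimulated, apoptosis, skeletal muscle and erythroid), where chance gives 3. Members past edgeR's test over all genes numbered 0 in every list. Adjusted over the list alone they numbered 28 for interferon-stimulated genes, 2 for dendritic cell markers, 1 each for chemokines, mesenchymal transition, epithelial and skeletal muscle genes, and 0 in each other list. Without 161-MAP-943 DESeq2 called, besides 12 interferon-stimulated genes and the members of other lists given above, 1 member higher in the proliferation and apoptosis lists each and 1 lower in the EMMPRIN, erythroid and immediate early lists each.

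Fold changes followed gene length across genes (Spearman rho 0.439 over the 12244 tested genes, which are not independent replicates, with the length that the FPKM values imply). With genes in 5 bins by length, the median log2 fold change was −0.39 in the bin with the shortest transcripts (median 1186 bp) and 0.41 in that with the longest (median 6361 bp). Scr-MAP-2 had the steepest slope towards short genes, and without it rho was 0.315. With a trend on length removed from each library, the edgeR test again called 0 genes and DESeq2 305 (194 higher, 111 lower), of which 237 were among the 540 called without that step. Among genes that passed DESeq2 before, Cd28, Klrk1, Ccr2 and Flt3 did not pass with the trend removed although their log2 fold changes moved little, to 2.61, 2.68, 1.63 and 3.39 from 2.84, 2.76, 1.72 and 3.48. Stxbp5, Nlrc5, Prrx1 and S100a4 did not pass either, with log2 fold changes of 0.68, 1.29, 0.66 and −0.40 against 1.08, 1.65, 0.996 and −1.31 before.

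**Figure D3:**
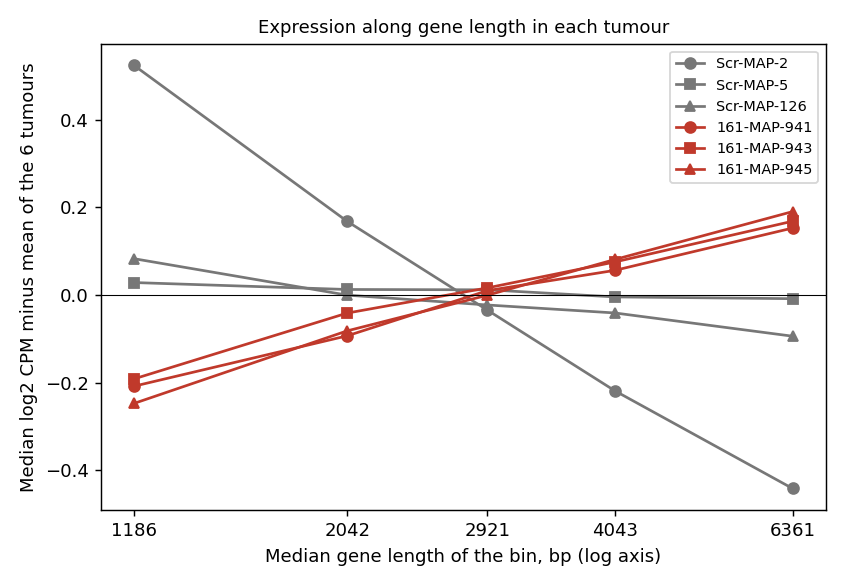
Median log2 CPM of genes in 5 bins by length in each tumour, minus the mean of the 6 tumours (y axis), against the median length of the bin in bp (x axis, log scale); Scr-MAP tumours are grey and 161-MAP tumours red. Scr-MAP-2 falls from 0.52 to −0.44 along length, while the 161-MAP tumours go from −0.25 to −0.19 for the shortest bin up to 0.15 to 0.19 for the longest.

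The deposited FPKM values, which are the counts divided by a library factor and a gene length and so are no independent measurement, also gave 0 genes. On the log2(FPKM + 1) scale, which understates changes of low genes, limma called 0 of 11299 genes at an adjusted p under 0.05, with 2261 at an unadjusted p under 0.05. With no filter on low values it called 3 genes, Lincenc1, 1700113B09Rik and Mir1191, all lower in 161-MAP, the last 2 of them named after their values were seen and resting on 4 or fewer counts per tumour.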

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

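The likelihood-ratio test, the length offsets, DESeq2 without single tumours and the contrast without 3 chemokines were chosen after the results were seen. Under the planned quasi-likelihood test the count of genes stayed 0 with every scaling, filter and threshold and without any single tumour. DESeq2 called 540 genes (294 higher, 246 lower), the likelihood-ratio test 204 (111 higher, 93 lower) and DESeq2 with length offsets 305 (194 higher, 111 lower). Without single tumours DESeq2 called 56 to 1042 genes, 37 to 603 of them higher and 19 to 487 lower. FPKM with no low-value filter gave 3 genes, and its other alternatives 0. The cause of these differences was not tested. The 7 lists became 0 with an estimated correlation, 0 by fry, 13 with length offsets and 3 to 14 without single tumours. The macrophage contrast kept its direction in all 10 alternatives (0.27 to 0.69).

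Medians of MHC class II (−0.98 to 1.62) and fibroblast genes (−0.80 to 1.83) turned without 161-MAP-943. For lists with no call whose median turned, such a median is given with each list, though not for every alternative. That of immediate early and stress genes ran from −0.52 to 0.20 over the alternatives. Among the genes picked for description, 85 kept their sign under all alternatives run. Without single tumours the log2 fold changes ran from −0.49 to 0.43 for Vegfa, −0.10 to 0.34 for Tgfb1, −0.60 to 2.25 for Cd79b, −0.27 to 3.34 for Tpsab1, −0.78 to 1.66 for H2-DMb2, −1.09 to 1.67 for H2-DMb1, −0.32 to 3.24 for Col1a1, −1.62 to 3.60 for Col3a1, −1.18 to 1.26 for Ttn, −0.39 to 0.73 for Sfn, −0.84 to 4.75 for Lpl and −0.15 to 0.83 for Egr2. Lgals7 was at 0.27 with length offsets, Sfn at −0.0147 with limma-voom and Bpgm at 0.0113 by library size alone. All 99 genes picked for description had a value under each alternative except a CPM of at least 1 in 3 libraries, which removed 2. Depth limits genes under about 1 CPM, such as Il2ra, Flt3 and Chil3 in Scr-MAP.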

Other observations

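Families outside the fixed lists were examined after the data were seen. All 8 measured Slfn genes, which are induced by interferon and restrict cell growth and viruses, were higher in 161-MAP (median log2 fold change 2.30, and 1.37 without 161-MAP-943), and DESeq2 called 5 of them. The same held for all 5 Apol genes (median 2.45, and 1.5 without 161-MAP-943, 4 called), all 8 Oas genes (median 1.65 and 0.88, 4 called) and all 11 Gbp genes (median 2.72 and 1.27, 7 called). The Oas and Gbp families share members with the interferon list, such as Oas2, Oas3, Gbp3 and Gbp5, and so repeat part of it. The Slfn and Apol genes are not in that list. Close paralogs within these families can share reads. Ribosomal protein genes went the other way, with 78 of 79 lower (median −1.14) and 56 called by DESeq2, but their transcripts are short, and with a length trend removed the median was −0.52 and DESeq2 called 1. Collagen genes were higher in 16 of 21 cases (median 0.74), and their median was −0.54 without 161-MAP-943.

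In what follows, the tests of single tumours, of leukocyte content, of length within a group and of genes near 0, and the splits for the edgeR and DESeq2 counts, were chosen after the result was seen, and the splits for lists and FPKM and the test of GC content before. The length offsets were chosen after fold changes were seen to follow length, but before their effect on the interferon list was seen. The 6 tumours allow 10 splits into 3 and 3, too few for a share under 0.05. DESeq2 called 540 genes in the real split and at most 279 in another, with 1 of the 10 as large. For the lists (7, highest other 21), 10 of the 10 splits were as large. With counts of 0 for edgeR and for FPKM (highest other 0 in both), 10 of the 10 splits are as large whatever they give, which decides nothing. The other 9 splits called 8 to 21 lists, and camera with its preset correlation called the interferon list in 9 of the 10 splits, so its calls do not set the groups apart from other splits.

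The first pattern is the higher level of interferon-stimulated genes in 161-MAP. 161-MAP-943 alone is argued against by the median of 1.20 without it, and the gene length trend by a median of 2.43 once that trend was removed. More leukocytes are argued against for 161-MAP-941 and 161-MAP-945, where the interferon list exceeded 20 pan-leukocyte genes (Ptprc, Coro1a, Laptm5 and others, 0 of them in the list) by 1.52 log2 units with the leukocyte median at −0.32, and by list means by 1.08 and 1.61 in these tumours against −0.14 to 0.16 in Scr-MAP tumours. In 161-MAP-943 they are argued against as the whole cause by a difference in list means of 1.49, but pan-leukocyte genes were also higher there, by a median of 1.67 against 3.23 for the interferon list, so a part in it stays open. The pan-leukocyte genes cover leukocytes as a whole, so this comparison does not address which kinds of leukocyte were present. The vaccine, and any difference in handling that went with the groups, stay open, and neither was tested.

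The second pattern is the rise of fold changes with gene length. Scr-MAP-2 alone is argued against by a rho of 0.315 without it, and GC content by a partial rho of 0.430 given GC. Length-dependent recovery of RNA cannot be told apart from a change that goes with the groups, since pairs within a group differ along length where they hold Scr-MAP-2 (rho −0.556 and −0.528) and little in the other 4 pairs (−0.055 to 0.105). The integrity of each RNA is not given in the sources used here, so whether it differed between the groups stays open. The DESeq2 calls of ribosomal protein genes went with the trend, from 56 to 1 when it was removed, as their median went from −1.14 to −0.52, and the DESeq2 count as a whole went from 540 to 305.

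The third pattern is a set of 4 genes, named after their values were seen, that were at least 8-fold higher in each Scr-MAP tumour than in any 161-MAP tumour. Counts over 3 tumours were 389 against 9 for Lincenc1 (ratio 51.6, 95% counting interval 26.9 to 114), 277 against 3 for Krt7 (110, 37.3 to 538), 173 against 1 for Pcdh10 (207, 36.6 to 8207) and 50 against 1 for Cdx2 (59.7, 10.2 to 2405). The test for skin, muscle, fat or nerve taken with the Scr-MAP tumours was left undecided by the muscle list alone. Its 3 measured genes had a median of −0.64 (0.38 over all 20, most of them near 0). The list summed to more CPM in each Scr-MAP tumour (12.4 to 19.2 against 5.52 to 10.2), but not without Tnni2. Other values argue against such tissue as the source. Muscle genes other than Tnni2 summed to 2.81 to 8.09 CPM in Scr-MAP and 4.93 to 8.46 CPM in 161-MAP tumours. Fat markers summed to less in each Scr-MAP tumour (468 to 537 against 795 to 832 CPM), and the sums of skin and of nerve markers overlapped. All sums of these tissue lists are of CPM scaled by library size alone. Different stocks or passages of CT26 cells may give such genes and cannot be told apart from the vaccine, whose effect on them was not tested, as the stock used per mouse is not given in the sources used here and the count of 4 compares with at most 3 in another split.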
